A study of Mus musculus with 32 samples.

How the data were processed

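RNA was measured by sequencing of poly(A)-selected RNA in 32 libraries of cultured mouse islets, 8 in each of 4 groups. Islets came from 10-week-old male and female mice on a C57BL/6NHsd background. The hIAPP mice carried the human gene for islet amyloid polypeptide (IAPP) in place of the mouse Iapp gene, put there by homologous recombination, and their wild-type littermates carried mouse Iapp and are called mIAPP. After isolation with collagenase and a night of recovery, islets of each genotype were cultured for 48 h at 11.1 or 16.7 mM glucose. Per the labels, 8 separate sets of experiments each held the 4 groups, and the number of a library marks its set; how many animals gave the islets of a set is not stated. Within each group, every library was assigned to its genotype, glucose level and set from its label, and 0 columns were left without a sample.

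The authors demultiplexed the reads with bcl2fastq 1.8.4 and quantified them with kallisto 0.45.0, with GRCm38 named as the genome build. The deposited values are expected counts (estimated reads per gene), given as whole numbers for 36595 Ensembl genes and not scaled to library size; how transcripts were summed and rounded is not stated. The deposited table summed to between 16.1 and 43.7 M per library. Positions and gene types were taken from GENCODE M21 on GRCm38, in which 35968 of the identifiers were found and 627 were not; 782 identifiers shared a symbol with another. The table held 0 long noncoding RNA genes of that annotation. Reads from the human insert are not separable here, because the labels do not say whether the human sequence was in the reference. The histology for which islets of each group were set aside was not analysed here.

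Counts were scaled with TMM in edgeR 4.0.16 under R 4.3.3, and filterByExpr by group left 16428 genes. All 32 libraries entered 1 quasi-likelihood fit (glmQLFit with robust estimation, glmQLFTest) with the 4 groups and the set as a block, which left 21 residual degrees of freedom. Its 5 comparisons were hIAPP against mIAPP islets at 16.7 mM and at 11.1 mM glucose, 16.7 against 11.1 mM glucose in hIAPP and in mIAPP islets, and the genotype by glucose interaction, which is the difference of the 2 genotype effects. Adjusted p values are Benjamini-Hochberg values over the genes tested in a comparison, and 0.05 was the threshold, with no minimum fold change. Log2 fold changes carry their standard error (SE) from the fit, and levels are TMM-scaled CPM with the standard deviation (SD) over the 8 libraries of a group. The pairing of libraries by set was checked on the values: after the group means were removed, profiles of the same set correlated across genes with a mean r of 0.14 to 0.31 between groups. For different sets the mean r was -0.043 to -0.019. Removing the group means ties these averages to the same-set ones, so they are no separate contrast. The lowest same-set r was -0.16 to 0.009, a library matched its own set best in 2 to 6 of 8 cases per pair of groups, and genes are not independent replicates. Without the replicate block the count for the genotype comparison at 16.7 mM glucose was 1301 and with it 3371.

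Genes were named by a rule: Star, which the series title names, and Iapp always; then up to 10 genes per direction with the largest change among those past the threshold, at a mean of at least 1 CPM and with the same sign of the within-set difference (pseudocount 0.5 CPM) in at least 7 of the 8 sets. Models without a symbol, Gm-numbered and Rik models and clone names were passed over, and genes named outside this rule are said to be so. From each list, up to 4 members with the smallest p could be named. For a group with 0 counts in all of its libraries the fold is a bound against a floor of 3 counts per library, and for 1 to 3 counts the ratio of totals has a 95% exact Poisson interval (these cover counting error only, since reads without molecular identifiers are not independent molecules). For a group with more counts but a mean below that floor, levels are given in place of a fold.

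Altogether 16 gene lists and 11 marker lists were tested with camera in limma 3.58.1 on voom values with the set as a block and an inter-gene correlation of 0.01, adjusted over 135 tests (27 lists in 5 comparisons). The gene lists covered beta cell identity and secretion, beta cell disallowed and dedifferentiation genes, ER stress and the unfolded protein response, NF-kB and inflammasome inflammation, interferon response, sterol transport and steroidogenesis, cholesterol biosynthesis, ChREBP and lipogenic glucose response, glycolysis, oxidative stress and metallothionein, apoptosis and p53, immediate early genes, proliferation, amyloid clearance and extracellular matrix, hypoxia, and mitochondrially encoded genes. The marker lists covered alpha, delta and PP, acinar, ductal, endothelial, stellate and fibroblast, macrophage, lymphocyte, neutrophil, and glial cells and Y-linked genes. Of all list members, 1 (Tmem27) was not matched. Fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, and camera with an estimated correlation were alternatives. Calls near the targeted locus were compared by distance from Iapp on chromosome 6 with those on other chromosomes by a two-sided Fisher exact test with a limit of 20 Mb, and with limits of 5 and 40 Mb as alternatives.

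The comparisons, lists, naming rule, distance test and the following alternatives were chosen before the data were examined: no block, a block crossed with genotype for the glucose comparisons and the interaction, only the 2 groups compared, DESeq2 size factors, TMM without acinar, mitochondrial and the most abundant genes, no count filter, at least 5 CPM in 8 libraries, DESeq2 1.42.0, limma voom with quality weights, covariates for acinar and Y-linked levels, and leaving out each set. A covariate for the level of mitochondrially encoded genes, the 18 libraries with under 10% mitochondrial counts, and the fit without the mIAPP library of set 7 at 16.7 mM glucose were added after the data were seen. Tests of lists were repeated with the first 2 of these. Exact sign-flip tests on within-set ratios, and 100 splits of the libraries with group labels swapped inside sets (fixed seed), are given at the end. Figures were drawn in Python 3.11.15.

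The fit was tested on simulated data with 16428 genes and the same group sizes. For the 4 pairwise comparisons edgeR recovered 53 to 56% of the genes with a 1.5-fold change and 72 to 76% of those with a 2-fold change, with 2.26 to 7.09% false calls. For the interaction it recovered 34% and 57.5%, with 4.19% false calls. Among 200 lists with no change, camera gave an unadjusted p under 0.05 for 1% and fry for 5%. The simulated genes were drawn independently of each other, with no set effect. These rates therefore do not show how often lists pass by chance where genes move together, as in the real libraries.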

Results

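Gene expression was measured in 32 libraries of cultured islets: 8 each of hIAPP islets at 16.7 mM glucose, mIAPP islets at 16.7 mM, hIAPP islets at 11.1 mM and mIAPP islets at 11.1 mM, with 1 library of each group in each of 8 experiment sets. Human IAPP forms amyloid deposits in islets and mouse IAPP does not, and the series title names islet amyloid formation, so the genotype comparison at 16.7 mM glucose, the interaction and the gene Star are at its centre. The total count per library was 31.5 ± 6.82 M (SD, n = 8) in hIAPP and 31.3 ± 4.53 M in mIAPP islets at 16.7 mM glucose. At 11.1 mM it was 25.5 ± 4.92 and 24.6 ± 4.11 M. The insulin genes took 17.9 to 20.2% of the counts on average in each group. At 16.7 mM the Y-linked genes together stood at 27.4, 26.2 and 27 CPM in hIAPP libraries of sets 2, 4 and 8. In mIAPP libraries of these sets they stood at 8.15, 8.71 and 9.13, and in set 1 at 173 and 145 in hIAPP and mIAPP. In set 5 they stood at 35.9 CPM in the mIAPP library at 11.1 mM, against 156 in the hIAPP library at 11.1 mM and 120 in the mIAPP library at 16.7 mM. In set 6 the mIAPP libraries were closer, at 171 and 152 at 11.1 and 16.7 mM. The mix of male and female islets thus differed between sets, and may have differed between genotypes and between glucose levels within some. The log2 fold changes below are given with their SE from 8 sets, and "set" with a number means the replicate of that number.

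Iapp (ENSMUSG00000041681, GRCm38 chromosome 6, 142298423 to 142303961), the hormone gene that was replaced in the hIAPP mice, was lower in hIAPP islets in all 8 sets at each glucose level. Its level was 10900 ± 593 CPM (SD, n = 8) in hIAPP and 24300 ± 4170 in mIAPP islets at 16.7 mM glucose, a log2 fold change of -1.14 ± 0.11 (SE, adjusted p = 4.21e-08). At 11.1 mM it was 6690 ± 788 against 11900 ± 2150, a log2 fold change of -0.83 ± 0.11 (adjusted p = 4.24e-05). No hIAPP library overlapped an mIAPP library at the same glucose level: the highest hIAPP values were 11580 and 7912, and the lowest mIAPP values 16860 and 8645. In the libraries with under 10% mitochondrial counts the change at 11.1 mM was -1.002, with an adjusted p of 0.0838. Iapp rose with glucose in both genotypes, by 0.71 ± 0.11 in hIAPP islets (adjusted p = 3.18e-06) and 1.02 ± 0.11 in mIAPP islets (adjusted p = 3.26e-08), and the difference of these changes, -0.31 ± 0.15, did not pass (adjusted p = 0.269). How many of the counts in hIAPP islets came from the human sequence is not known.

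Star (ENSMUSG00000031574, chromosome 8, 25806555 to 25815982) encodes the steroidogenic acute regulatory protein, which carries cholesterol to the inner mitochondrial membrane. It was 7.67-fold higher in hIAPP than in mIAPP islets at 16.7 mM glucose, at 140 ± 56 against 17.2 ± 3.24 CPM (SD, n = 8; log2 2.94 ± 0.19, SE, adjusted p = 3.68e-11), and higher in 8 of 8 sets. At 11.1 mM glucose Star did not differ past the threshold: 10.4 ± 4.21 against 8.88 ± 2.63 CPM, log2 0.19 ± 0.19 (adjusted p = 0.826), higher in 5 sets and lower in 3. Star rose with glucose 13.3-fold in hIAPP islets (log2 3.73 ± 0.20, adjusted p = 9.32e-14) and 1.98-fold in mIAPP islets (0.98 ± 0.19, adjusted p = 0.000133), in 8 of 8 sets each. The genotype by glucose interaction was 2.75 ± 0.26 (adjusted p = 1.35e-06).

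**Figure D1:**
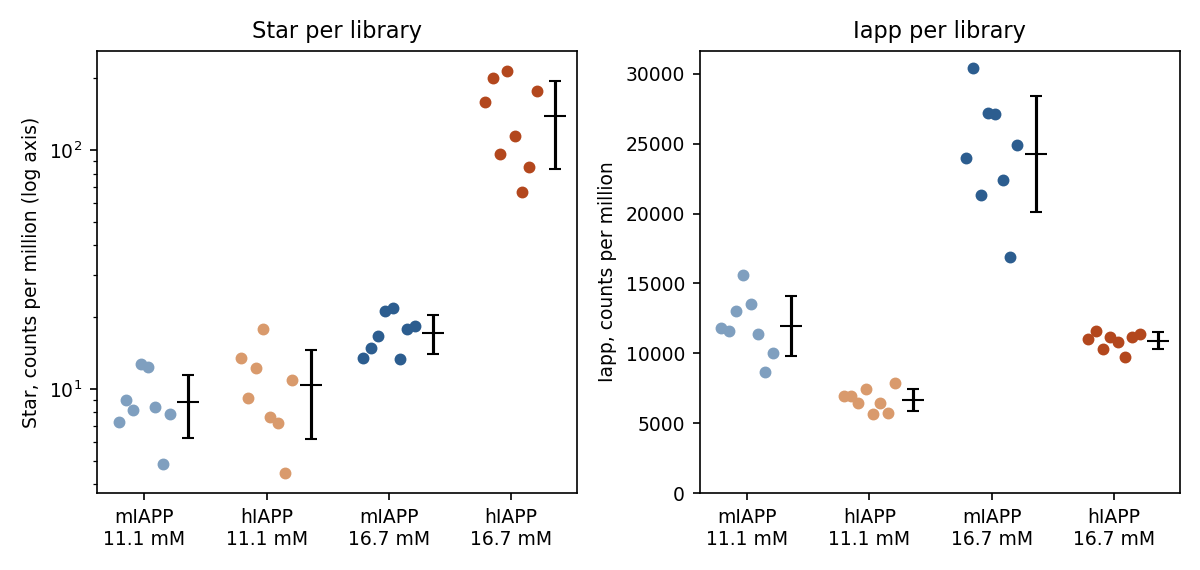
Star (left, log axis) and Iapp (right) in CPM for each library of the 4 groups; points are libraries in the order of the sets, and the black mark with bars beside them is the mean ± SD (n = 8). Star in hIAPP islets at 16.7 mM glucose lay between 67.05 and 215.1 and in mIAPP islets at that level between 13.35 and 21.81.

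The share of mitochondrially encoded counts moved with the groups and also varied within them. It was 4.06 ± 1.63% (SD, n = 8) in hIAPP islets at 16.7 mM glucose, 11.3 ± 11.2% in mIAPP islets at 16.7 mM, 16.6 ± 7.82% in hIAPP islets at 11.1 mM and 18.2 ± 11.6% in mIAPP islets at 11.1 mM. The mIAPP library of set 7 at 16.7 mM had 37%, with 13.4% the next highest of its group. All 8 hIAPP libraries at 16.7 mM lay under 10%, with 5, 2 and 3 libraries of the other groups, in that order. Within mIAPP islets at 11.1 mM the share ran from 3.49 to 34.7%. The share of pseudogene counts was 1.11, 1.6, 2.47 and 2.54% in the 4 groups, in the order above. The first principal component, the axis along which libraries differ most, held 47.4% of the variance. Its Pearson r with the mitochondrial level was -0.958. Whether library quality lies behind this was not tested.

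**Figure D2:**
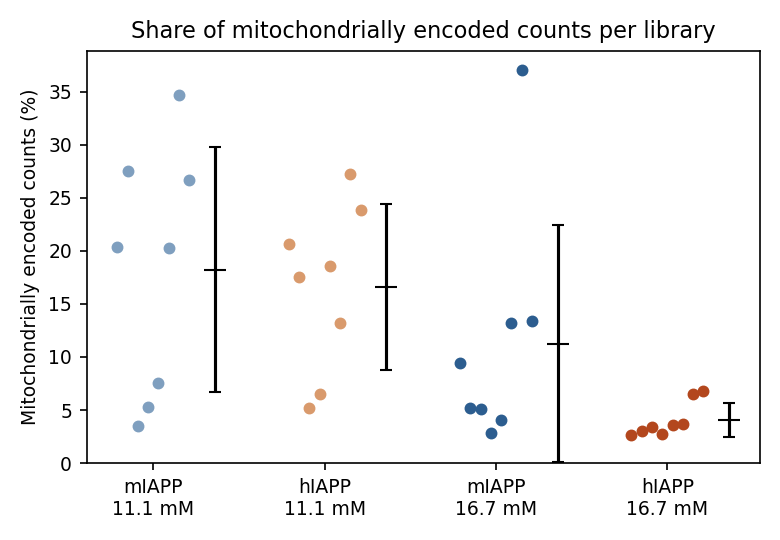
Mitochondrially encoded counts as a percentage of all counts in each library of the 4 groups; points are libraries in the order of the sets, and the black mark with bars is the mean ± SD (n = 8). The hIAPP libraries at 16.7 mM glucose lay between 2.68 and 6.76%.

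Comparing hIAPP with mIAPP islets at 16.7 mM glucose asks what differs where human IAPP is made at high glucose. Inflammatory mediators stood out among the rises. Cxcl1, a chemokine that attracts neutrophils, rose by log2 5.63 ± 0.53 (SE; 8.11 ± 3.63 against 0.175 ± 0.204 CPM, SD, n = 8, adjusted p = 4.26e-08), and Ccl2, which attracts monocytes, by 4.59 ± 0.56 (adjusted p = 2.02e-06). S100a9, an alarmin of myeloid cells, was at least 48.1-fold higher, with 4.86 ± 7.29 CPM in hIAPP islets and 0 counts in all 8 mIAPP libraries, and at least 22.9-fold higher when set 6 with 22.7 CPM was left out. Steap4, a metalloreductase that cytokines induce, rose by 3.99 ± 0.33 (adjusted p = 3.62e-09), Lama3, a laminin chain of epithelial basement membranes, by 4.56 ± 0.43 (adjusted p = 7.52e-08), and Sprr1a, a protein of the epithelial stress response, by 5.11 ± 0.54 (adjusted p = 6.13e-07). The borate and water transporter Slc4a11 rose by 3.65 ± 0.44 (adjusted p = 1.71e-06), each of these genes in 8 of 8 sets.

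Some of the remaining large changes lie in gene families or spans whose reads are hard to assign. Rdh16f1, a retinol dehydrogenase paralog, was higher (4.23 ± 2.84 CPM against 0.0847 CPM, below the floor of 3 counts per library; adjusted p = 4.74e-06), while Rdh9, whose span on chromosome 10 overlaps it, fell by log2 1.94 ± 0.56 (adjusted p = 0.0178), so neither is certain. Without set 1, 2 or 6, Rdh9 did not pass (-1.95, -1.65 and -1.61). The olfactory receptor gene Olfr552 and the histone gene Hist1h2aa rose at both glucose levels, here Olfr552 by 4.20 ± 0.23 (adjusted p = 1.11e-12) and Hist1h2aa to 1.56 CPM from 0.0229 CPM, below the floor (adjusted p = 3.38e-10). The largest falls were mostly of genes at low levels: Olfr907 (-2.30 ± 0.69), Tbata (-2.25 ± 0.70), Vmn2r52 (-2.07 ± 0.56), Vmn2r100 (-2.02 ± 0.54), Olfr620 (-1.99 ± 0.52), Siglecg (-1.95 ± 0.51) and Slc1a3 (-1.87 ± 0.47). Leaving out set 7 ended each of these 7 calls, with -1.68, -1.86, -1.41, -1.65, -1.50, -1.54 and -1.35, and a covariate for the mitochondrial level left 1 of the 10 falls. Mid1, an X-linked ubiquitin ligase gene, fell by 1.90 ± 0.31 (30.1 ± 13.2 against 117.6 ± 54.1 CPM, adjusted p = 0.000144; 8 of 8 sets), and was the 1 that stayed. Rpgrip1, a gene of the photoreceptor cilium, fell by 2.03 ± 0.46 (adjusted p = 0.00368) and to -0.95 with that covariate, which did not pass.

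Inflammatory and sterol genes rose as groups. Of 27 measured genes of the NF-kB and inflammasome list, 15 rose and 0 fell (18 and 2 adjusted over the list alone), with a median log2 fold change of 1.09 (camera adjusted p = 4.16e-09, adjusted p = 0.167 with an estimated correlation). Besides the chemokines above, Nos2, the inducible nitric oxide synthase, rose by 4.04 ± 0.56 (adjusted p = 1.08e-05) and Birc3, an NF-kB target that restrains cell death, by 1.06 ± 0.12 (adjusted p = 1.12e-06). Cholesterol biosynthesis genes rose in 19 of 23 cases and fell in 0 (20 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 2.29e-13, adjusted p = 0.216 with an estimated correlation). Among them, Msmo1, a sterol demethylation enzyme, rose by 0.88 ± 0.11 (adjusted p = 1.56e-06) and Sqle, the squalene epoxidase, by 0.84 ± 0.12 (adjusted p = 1.68e-05). Immediate early genes rose in 12 of 19 cases and fell in 1 (13 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 1.6e-05, adjusted p = 0.216 with an estimated correlation). The nuclear receptor Nr4a2 (1.17 ± 0.12, adjusted p = 1.96e-07) and the phosphatase Dusp1 (1.26 ± 0.14, adjusted p = 5.06e-07) led them.

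Metabolic and stress lists also moved up, with fewer members past the threshold. Of the glycolysis genes 6 of 18 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 4.99e-05, adjusted p = 0.601 with an estimated correlation). Pfkp, a phosphofructokinase, was among them (1.05 ± 0.14, adjusted p = 9.16e-06). For the ER stress list 4 of 23 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.0162, adjusted p = 0.601 with an estimated correlation). The transcription factor Atf3 rose most clearly (1.55 ± 0.17, adjusted p = 3.98e-07). Oxidative stress genes rose in 9 of 21 cases and fell in 2 (10 and 3 adjusted over the list alone, median 0.16, camera adjusted p = 0.0195, adjusted p = 0.601 with an estimated correlation). Srxn1, the sulfiredoxin, rose by 0.69 ± 0.07 (adjusted p = 2.31e-07). Hypoxia genes rose in 5 of 15 cases and fell in 2 (6 and 2 adjusted over the list alone, median 0.35, camera adjusted p = 0.0392, adjusted p = 0.601 with an estimated correlation). Of the 4 ER stress genes, Edem1 (0.36, 0.41, 0.40 and 0.35) and Pdia6 (0.31, 0.35, 0.32 and 0.23) did not pass without set 1, 2, 6 or 7, nor without the mIAPP library of set 7 at 16.7 mM (0.39 and 0.28). With the mitochondrial covariate the ER stress and hypoxia lists did not pass (adjusted p = 0.698 and 0.0844).

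Beta cell, endothelial and mitochondrial genes moved down. Of 24 beta cell identity genes 11 fell and 2 rose (12 and 2 adjusted over the list alone, median -0.26, camera adjusted p = 0.00971, adjusted p = 0.601 with an estimated correlation). Nkx6-1, a transcription factor of beta cell identity, fell by 0.71 ± 0.10 (adjusted p = 1.86e-05), Ucn3, a peptide of mature beta cells, by 0.67 ± 0.12 (adjusted p = 0.00023) and Trpm5, a cation channel, by 1.08 ± 0.17 (adjusted p = 4.86e-05). Endothelial markers fell in 8 of 14 cases and rose in 0 (11 and 0 adjusted over the list alone, median -0.74, camera adjusted p = 1.19e-05, adjusted p = 0.601 with an estimated correlation). Examples were Pecam1 (-1.16 ± 0.22, adjusted p = 0.000536) and Cldn5, a tight junction gene (-1.54 ± 0.30). Mitochondrially encoded genes fell in 12 of 13 cases (13 adjusted over the list alone, median -1.29, camera adjusted p = 2.47e-06, adjusted p = 0.601 with an estimated correlation). The mitochondrial share, 4.06% against 11.3% on average (medians 3.5 and 7.28%), is taken from the same genes and is no separate evidence. With the mitochondrial covariate Pecam1 was at -0.74 with an adjusted p of 0.0697. Without set 7, mt-Cytb (-0.89), mt-Nd2 (-1.07) and mt-Nd5 (-0.96) did not pass, nor did mt-Cytb without set 6 (-1.08).

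The remaining lists did not pass camera. Members that rose and fell were 1 and 5 of 20 macrophage markers (median -0.15, adjusted p = 0.256), 5 and 0 of 22 interferon genes, 3 and 2 of 16 sterol transport genes including Star, 5 and 2 of 20 ChREBP genes, and 4 and 3 of 20 apoptosis genes. They were 1 and 1 of 18 beta cell disallowed genes, 4 and 1 of 23 amyloid clearance and matrix genes, 0 and 1 of 20 proliferation genes, 3 and 0 of 13 ductal markers, and 0 and 2 of 18 stellate markers. For other cells they were 0 and 1 of 11 alpha, 0 and 0 of 9 delta and PP, 0 and 0 of 22 acinar, 0 and 2 of 7 lymphocyte, 1 and 1 of 3 neutrophil, 0 and 1 of 8 glial markers, and 1 and 0 of 4 Y-linked genes. For alpha markers the median was -0.02 and the mean 0.04, and of the neutrophil markers S100a9 was the 1 that rose.

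In all, 3371 genes passed at 16.7 mM glucose, 1523 higher and 1848 lower in hIAPP islets, and 248 and 404 of them changed by more than 2-fold. Without the replicate block 1301 passed, limma voom gave 8240, the mitochondrial covariate 898, and the libraries with under 10% mitochondrial counts 1149. Leaving out set 1, 2, 6 or 7 gave 1623, 2215, 1852 and 1943 genes, leaving out only the mIAPP library of set 7 gave 2108, and as many lists passed in 32 of 100 splits with genotype swapped inside sets.

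At 11.1 mM glucose the same comparison asks which genotype differences exist at the lower glucose level. Few genes differed. Besides Iapp, 7 called genes lie within 20 Mb of it on chromosome 6, 6 of them higher. Hebp1, a heme-binding protein gene, rose by log2 1.30 ± 0.14 (SE; 7.17 ± 1.56 against 2.92 ± 0.864 CPM, SD, n = 8, adjusted p = 2.52e-06). Pik3c2g, a lipid kinase gene, rose by 1.23 ± 0.22 (adjusted p = 0.00764) and Gprc5a, an orphan receptor gene, by 1.30 ± 0.26 (adjusted p = 0.0252). On other chromosomes Zfp488, a zinc finger gene, rose by 1.51 ± 0.11 (103.1 ± 14.8 against 36.8 ± 9.79 CPM, adjusted p = 6.25e-10; 8 of 8 sets). Mid1 was at -1.799 ± 0.31 (54.1 ± 37.1 against 198.4 ± 149 CPM, adjusted p = 0.00656; 7 of 8 sets).

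Further rises were in gene families whose reads can be shared. Olfr552 rose by log2 3.16 ± 0.22 (adjusted p = 4.12e-10), Olfr1238 by 2.30 ± 0.15 (adjusted p = 9.32e-11), Vmn1r213 by 2.00 ± 0.15 (adjusted p = 1.26e-09) and Olfr477 by 1.53 ± 0.19 (adjusted p = 2.6e-05); these encode olfactory and vomeronasal receptors. Cks1brt, a retrogene, rose by 3.79 ± 0.36 (adjusted p = 8.91e-08). Hist1h2aa had 2 counts in all mIAPP libraries together, and its ratio of totals was 255 (95% counting interval 70.2 to 2110). The other called genes were chosen for mention after their values were seen: Nudcd1 (1.00 ± 0.08), Gpr19 (1.09 ± 0.09), Gm13722 (1.32 ± 0.12), BC049715 (1.55 ± 0.21), Slco1a5 (0.72 ± 0.13), Nr4a1 (0.96 ± 0.19) and Gm47632 (1.07 ± 0.22) were higher. With the lower group below the floor, Gm7291 was higher (1.13 against 0.0625 CPM, adjusted p = 0.00255) and Art4 lower (0.0602 against 0.735 CPM, adjusted p = 0.00994).

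The calls at this level were 21 of 16428, 18 higher and 3 lower, with 1121 genes at an unadjusted p under 0.05. DESeq2 gave 35, limma voom 46, a minimum of 5 CPM 13, and the libraries with under 10% mitochondrial counts 11. Within 20 Mb of Iapp, 7 of 198 tested genes passed (3.54%), against 13 of 15404 on other chromosomes (0.0844%), an odds ratio of 43.3 (95% interval 14.5 to 118; Fisher exact p = 3.21e-09); 0 of 603 genes farther off on chromosome 6 passed. At 16.7 mM glucose the same shares were 52 of 198 (26.3%) and 3168 of 15404 (20.6%), with an odds ratio of 1.38 (0.98 to 1.91; Fisher exact p = 0.052). The calls of Gprc5a and Mid1 did not stand without 1 of several sets. Gprc5a was at 1.27, 1.22, 1.26, 1.28, 1.13 and 1.32 without set 1, 2, 4, 6, 7 or 8. Mid1 was at -1.70, -1.75, -1.75 and -1.72 without set 2, 3, 4 or 5. Pik3c2g was at 1.14 and 1.23 without set 3 or 4, and Slco1a5 at 0.72, 0.70, 0.70 and 0.71 without set 1, 2, 3 or 8. Art4 did not pass without set 1, 2 or 8. Nr4a1, at 0.86 to 0.99, passed only without set 3, and Gm47632, at 0.89 to 1.16, only without set 7.

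**Figure D3:**
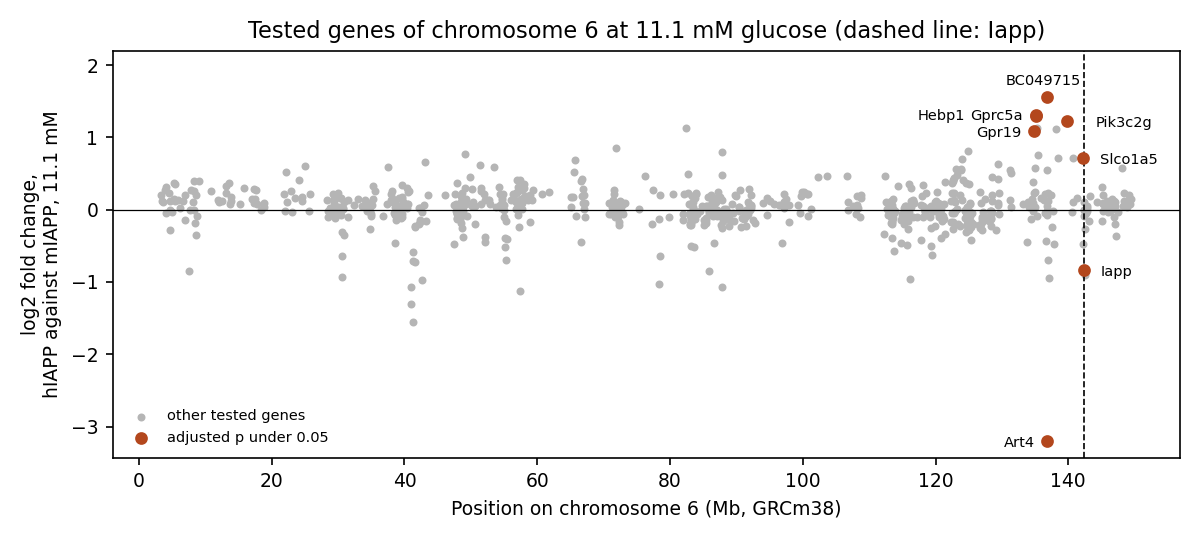
Log2 fold change of hIAPP against mIAPP islets at 11.1 mM glucose (vertical axis) for each tested gene of chromosome 6 by its position in Mb on GRCm38 (horizontal axis); red points had an adjusted p under 0.05 (8 libraries per group) and the dashed line marks Iapp. Called genes lay within 20 Mb of Iapp.

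Among the lists at 11.1 mM glucose, no list with a called member passed camera, and in the edgeR fit the single list gene past the threshold was the immediate early gene Nr4a1 (1 of 19 genes higher; 3 adjusted over the list alone). Camera passed 4 lists with 0 members past the threshold: macrophage markers (median 0.15, adjusted p = 0.00103) and glycolysis (median 0.07, adjusted p = 0.0259) higher, and endothelial markers (median -0.21, adjusted p = 0.00172) and acinar markers (median -0.75, adjusted p = 0.0196) lower. They had adjusted p = 0.601, 0.739, 0.601 and 0.785 with an estimated correlation, fry passed 0 lists, and as many lists passed in 82 of 100 splits. The log2 fold changes at this level also moved with GC content (Spearman r -0.514 across genes, which are not independent replicates).

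In hIAPP islets, 16.7 against 11.1 mM glucose asks how these islets respond to the higher glucose level. Star rose, and Cxcl1, S100a9, Sprr1a, Lama3 and the neuropeptide gene Tac1 were among the 10 largest rises, beside pseudogenes. Cxcl1 rose to 8.11 ± 3.63 CPM from 0.0721 ± 0.0904 CPM (SD, n = 8, adjusted p = 7.44e-10) and Tac1, the precursor of substance P, to 4.27 ± 3.96 from 0.065 ± 0.0934 CPM (adjusted p = 1.61e-09), both from below the floor. Sprr1a rose by log2 5.38 ± 0.54 (SE, adjusted p = 2.19e-08) and Lama3 by 5.27 ± 0.45 (adjusted p = 1.01e-09). S100a9 rose from 0.0219 ± 0.0451 CPM, below the floor, to 4.86 ± 7.29 CPM, or 2.32 CPM without set 6 (adjusted p = 1.2e-08), and Rdh16f1 was at least 33.5-fold higher, with 0 counts in all 8 libraries at 11.1 mM. Fam196a, an inhibitory synapse gene, fell by 3.66 ± 0.29 (adjusted p = 1.04e-10), and Klf10, a transcription factor gene, was at -3.42 ± 0.82 (adjusted p = 0.00103), although Klf10 was at 0.53 with the mitochondrial covariate. Several of the 10 largest changes in each direction were processed pseudogenes with uncertain reads, such as Sms-ps (5.96 ± 1.11) and Rpl17-ps8 (-5.30 ± 1.32), and the covariate left 6 of the 10 rises and 2 of the 10 falls.

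Secretory stress genes and sterol genes rose together in hIAPP islets with glucose. Of 23 ER stress genes 21 rose and 2 fell (21 and 2 adjusted over the list alone, median 1.29, camera adjusted p = 4.75e-11, adjusted p = 0.167 with an estimated correlation). Examples were Sdf2l1, an ER chaperone cofactor (2.18 ± 0.12, adjusted p = 1.59e-13), and Creld2, an ER stress-inducible factor (1.56 ± 0.07, adjusted p = 3.76e-15). Cholesterol biosynthesis genes rose in 20 of 23 cases and fell in 0 (20 and 0 adjusted over the list alone, median 0.95, camera adjusted p = 2.77e-07, adjusted p = 0.601 with an estimated correlation). Sqle was at 1.71 ± 0.12 (adjusted p = 1.55e-11). Immediate early genes rose in 15 of 19 cases and fell in 2 (15 and 2 adjusted over the list alone, median 1.18, camera adjusted p = 0.000129, adjusted p = 0.295 with an estimated correlation). Nr4a2 led them (3.36 ± 0.14, adjusted p = 1.41e-15). Glycolysis genes rose in 13 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone, median 0.69, camera adjusted p = 0.00108, adjusted p = 0.601 with an estimated correlation). Oxidative stress genes rose in 11 of 21 cases, with 4 lower (11 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 0.0466, adjusted p = 0.601 with an estimated correlation).

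Markers of other cells and some beta cell genes fell in hIAPP islets with glucose. Families outside these lists, examined only after the data were seen, fell as well. Olfactory receptor genes were lower in 201 of 244 cases (7 higher, median -1.26) and vomeronasal ones in 103 of 129 (1 higher, -1.21). With the mitochondrial covariate 8 and 2 were lower and 6 and 2 higher, at medians of -0.13 and 0.02. The marker falls alone therefore do not show a loss of those cells. Macrophage markers fell in 17 of 20 cases and rose in 0 (17 and 0 adjusted over the list alone, median -1.33, camera adjusted p = 5.82e-07, adjusted p = 0.601 with an estimated correlation). Among them were the class II invariant chain Cd74 (-2.02 ± 0.17, adjusted p = 3.04e-10) and the receptor Csf1r (-1.53 ± 0.14). Endothelial markers fell in 13 of 14 cases (13 adjusted over the list alone, median -1.24, camera adjusted p = 0.000322, adjusted p = 0.601 with an estimated correlation) and stellate markers in 13 of 18 (13 adjusted over the list alone, median -0.67, camera adjusted p = 0.00451, adjusted p = 0.73 with an estimated correlation). Beta cell identity genes fell in 16 of 24 cases and rose in 4 (16 and 4 adjusted over the list alone, median -0.31, camera adjusted p = 0.045, adjusted p = 0.601 with an estimated correlation). Trpm5 was at -3.02 ± 0.17 and the insulin transcription factor Mafa at -1.18 ± 0.12, while the glucose-6-phosphatase gene G6pc2 rose by 1.18 ± 0.12. Mitochondrially encoded genes fell in 13 of 13 cases (13 adjusted over the list alone, median -2.07, camera adjusted p = 4.99e-05, adjusted p = 0.601 with an estimated correlation). The mitochondrial share, taken from the same genes, was 4.06% against 16.6%.

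The fit called 10768 genes in hIAPP islets, 5294 higher and 5474 lower at 16.7 mM glucose, of which 1349 and 2136 changed by more than 2-fold. With the mitochondrial covariate 4169 genes passed, and in the libraries with under 10% mitochondrial counts, 2 of them hIAPP at 11.1 mM, 3916 did. As many lists passed in 34 of 100 splits with glucose swapped inside sets.

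In mIAPP islets, which make no human IAPP, the same glucose comparison gives the response without it. The largest rises were of Mc5r, a melanocortin receptor gene (log2 5.13 ± 0.39, SE; 10.1 ± 3.53 against 0.292 ± 0.208 CPM, SD, n = 8, adjusted p = 1.27e-10). Next were Serpina7, which encodes thyroxine-binding globulin (4.77 ± 0.26, adjusted p = 7.33e-13), and Sgcd, a sarcoglycan gene (3.70 ± 0.33, adjusted p = 2.55e-09). The activity-induced transcription factors Nr4a1 and Npas4 rose by 3.39 ± 0.20 and 3.26 ± 0.24 (adjusted p = 1.14e-12 and 6.51e-11), and Pappa2, a protease of growth factor binding proteins, by 3.34 ± 0.24 (adjusted p = 6.59e-11). Among the falls, Fam196a was at -2.98 ± 0.28 (adjusted p = 7.36e-09), the histamine receptor gene Hrh3 at -2.48 ± 0.29 (adjusted p = 1.77e-07), and the B cell genes Cd79a and Ighm at -2.10 ± 0.18 and -1.87 ± 0.30 (adjusted p = 1.45e-09 and 2.25e-05).

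Glucose moved many of the same gene lists in mIAPP islets. ER stress genes rose in 20 of 23 cases and fell in 2 (20 and 2 adjusted over the list alone, median 1.06, camera adjusted p = 2.29e-13, adjusted p = 0.167 with an estimated correlation). Creld2 was at 1.54 ± 0.07 (adjusted p = 2.28e-14). Cholesterol biosynthesis genes rose in 13 of 23 cases and fell in 2 (13 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.0178, adjusted p = 0.73 with an estimated correlation), and did not pass with the mitochondrial covariate (adjusted p = 0.0767). Glycolysis genes rose in 10 of 18 cases and fell in 2 (10 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 0.0123, adjusted p = 0.73 with an estimated correlation). Immediate early genes rose in 9 of 19 cases and fell in 3 (9 and 4 adjusted over the list alone, median 0.38, camera adjusted p = 0.0178, adjusted p = 0.601 with an estimated correlation). Interferon genes fell in 9 of 22 cases and rose in 5 (12 and 5 adjusted over the list alone, median -0.43, camera adjusted p = 0.0238, adjusted p = 0.601 with an estimated correlation). In the interferon list the immunoproteasome gene Psmb9 was at -1.03 and the antiviral gene Rsad2 rose by 1.16 ± 0.19.

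Macrophage markers fell with glucose in 17 of 20 cases in mIAPP islets too (17 adjusted over the list alone, median -0.995, camera adjusted p = 2.64e-07, adjusted p = 0.601 with an estimated correlation). Csf1r was among them (-1.16 ± 0.14, adjusted p = 2.71e-07). Endothelial markers fell in 8 of 14 cases (9 adjusted over the list alone, median -0.70, camera adjusted p = 0.00172, adjusted p = 0.601 with an estimated correlation). Stellate markers fell in 7 of 18 (6 adjusted over the list alone, median -0.50, camera adjusted p = 0.00805, adjusted p = 0.73 with an estimated correlation). Mitochondrially encoded genes fell in 3 of 13 cases (0 adjusted over the list alone, median -0.83, camera adjusted p = 0.0288, adjusted p = 0.8 with an estimated correlation). The mitochondrial share, taken from the same genes, was 11.3% against 18.2%. The beta cell identity list did not pass (median -0.10, adjusted p = 0.37), with 4 genes higher and 8 lower (4 and 9 adjusted over the list alone). In all, 7805 genes passed, 4083 higher and 3722 lower, with 583 and 584 over 2-fold; as many lists passed in 22 of 100 splits.

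Most genes that changed with glucose in mIAPP islets changed the same way in hIAPP islets. Of 4083 genes that rose in mIAPP islets 3620 also rose in hIAPP islets, where independent calls would share 1320, and of 3722 that fell 3209 also fell, against 1240. Only 11 and 20 genes moved in opposite directions, and the covariance of the log2 fold changes across genes was 0.495 (Pearson r 0.789 across genes, which are not independent replicates). For genotype, 16 of the 18 genes higher at 11.1 mM glucose were among the 1523 higher at 16.7 mM (1.67 if independent), and 3 of the 3 lower genes were among the 1848 lower there (0.337 if independent). Their covariance was 0.0137 (Pearson r 0.078 across genes). These pairs of comparisons use separate libraries, although libraries of a set may come from the same islet preparations.

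The genotype by glucose interaction tests whether hIAPP and mIAPP islets differ in their response to glucose. Beside Star, Cxcl1, Ccl2 and several other genes with large genotype differences were higher in hIAPP islets at 16.7 mM than the separate effects add up to. Cxcl1 (adjusted p = 0.00154) and Tac1 (adjusted p = 0.00215) lay below the floor at 11.1 mM in both genotypes, so no size is given here. Sprr1a was higher by log2 4.81 ± 0.81 (SE, n = 8 sets, adjusted p = 0.00106) and Lama3 by 4.33 ± 0.65 (adjusted p = 3e-04). Ccl2 was higher by 4.19 ± 0.85 (adjusted p = 0.00454) and Steap4 by 4.06 ± 0.48 (adjusted p = 1.48e-05). Slc4a11 (3.59 ± 0.62) and Klhl1, an actin-binding gene of neurons (3.19 ± 0.78, adjusted p = 0.0199), followed. Among the lower ones, Npas4 was at -1.68 ± 0.32 (adjusted p = 0.0028), so its rise with glucose was smaller in hIAPP islets. Cib3, a calcium-binding gene, was at -1.70 ± 0.24 (adjusted p = 0.000104), with 7.35 CPM in hIAPP islets at 16.7 mM and 75.5 at 11.1 mM. Hpgd, which degrades prostaglandins, was at -1.96 ± 0.49 (adjusted p = 0.0234). Of the 10 largest interaction rises 10 passed without the replicate block and with the mitochondrial covariate, and 1 in the libraries with under 10% mitochondrial counts, and of the 10 largest falls 4, 4 and 0 did. Without set 1 the calls of Ccl2 and Klhl1 ended (3.85 and 2.91), as did that of Klhl1 without set 2 or 6 (2.78 and 3.18) and that of Hpgd without set 1, 2, 3, 4 or 8 (-1.93, -1.75, -1.81, -1.83 and -2.02).

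Inflammation and sterol lists were higher in the interaction, with few members past the threshold. NF-kB and inflammasome genes passed in 5 of 27 cases, all higher (15 higher and 1 lower adjusted over the list alone, median 0.91, camera adjusted p = 2.64e-07, adjusted p = 0.216 with an estimated correlation). Nos2 was among them (4.24 ± 0.76, adjusted p = 0.00151). Cholesterol biosynthesis genes passed in 7 of 23 cases, all higher (18 higher adjusted over the list alone, median 0.54, camera adjusted p = 3.75e-14, adjusted p = 0.216 with an estimated correlation). Msmo1 was among them (0.77 ± 0.15, adjusted p = 0.00327). Immediate early genes were higher in 6 of 19 cases and lower in 2 (9 and 2 adjusted over the list alone, median 0.45, camera adjusted p = 0.000525, adjusted p = 0.453 with an estimated correlation). Glycolysis had 1 of 18 genes higher, Pfkp (2 higher adjusted over the list alone, median 0.19, camera adjusted p = 0.00334, adjusted p = 0.616 with an estimated correlation). Pfkp did not pass without set 1, 2, 6 or 8 (0.78, 0.74, 0.77 and 0.84). ER stress had 1 of 23, Atf3 at 1.45 ± 0.24 (1 adjusted over the list alone, median 0.11, camera adjusted p = 0.0274, adjusted p = 0.601 with an estimated correlation).

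Lower in the interaction were beta cell identity genes in 2 of 24 cases, Trpm5 (-1.17 ± 0.23, adjusted p = 0.00348) and Nkx6-1 (-0.57 ± 0.14, adjusted p = 0.0257), with 8 lower and 1 higher adjusted over the list alone (median -0.19, camera adjusted p = 0.00379, adjusted p = 0.601 with an estimated correlation). Without set 1, 2, 4, 6 or 8 the call of Nkx6-1 ended (-0.56, -0.51, -0.52, -0.57 and -0.48). Macrophage markers were lower in 1 of 20 cases (3 adjusted over the list alone, median -0.36, camera adjusted p = 0.00418, adjusted p = 0.638 with an estimated correlation). The 1 was Cd74 (-0.82 ± 0.23, adjusted p = 0.0485), whose call ended without set 1, 2, 4, 6, 7 or 8 (-0.68, -0.74, -0.77, -0.82, -0.83 and -0.87) and without the mIAPP library of set 7 at 16.7 mM glucose (-0.76). Endothelial markers (median -0.61, camera adjusted p = 0.00172, adjusted p = 0.601 with an estimated correlation) and mitochondrially encoded genes (median -1.27, camera adjusted p = 1.3e-06, adjusted p = 0.601 with an estimated correlation) had 0 members past the threshold over all genes, with 3 and 12 lower adjusted over the list alone. The mitochondrial share, taken from the same mitochondrially encoded genes, was lowest, at 4.06%, in hIAPP islets at 16.7 mM glucose.

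The interaction passed for 513 genes, 357 higher and 156 lower, of which 351 and 150 were also higher and lower in hIAPP islets at 16.7 mM glucose, a comparison that shares those libraries. Of the 357, 160 rose with glucose in both genotypes and 159 changed in hIAPP islets without passing in mIAPP islets. Without the replicate block 196 genes passed, DESeq2 gave 959, limma voom 4711, a Y-linked covariate 953, the mitochondrial covariate 304 and the libraries with under 10% mitochondrial counts 8. Leaving out set 1, 2, 6 or 8 gave 239, 310, 280 and 337, and as many lists passed in 14 of 100 splits.

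**Figure D4:**
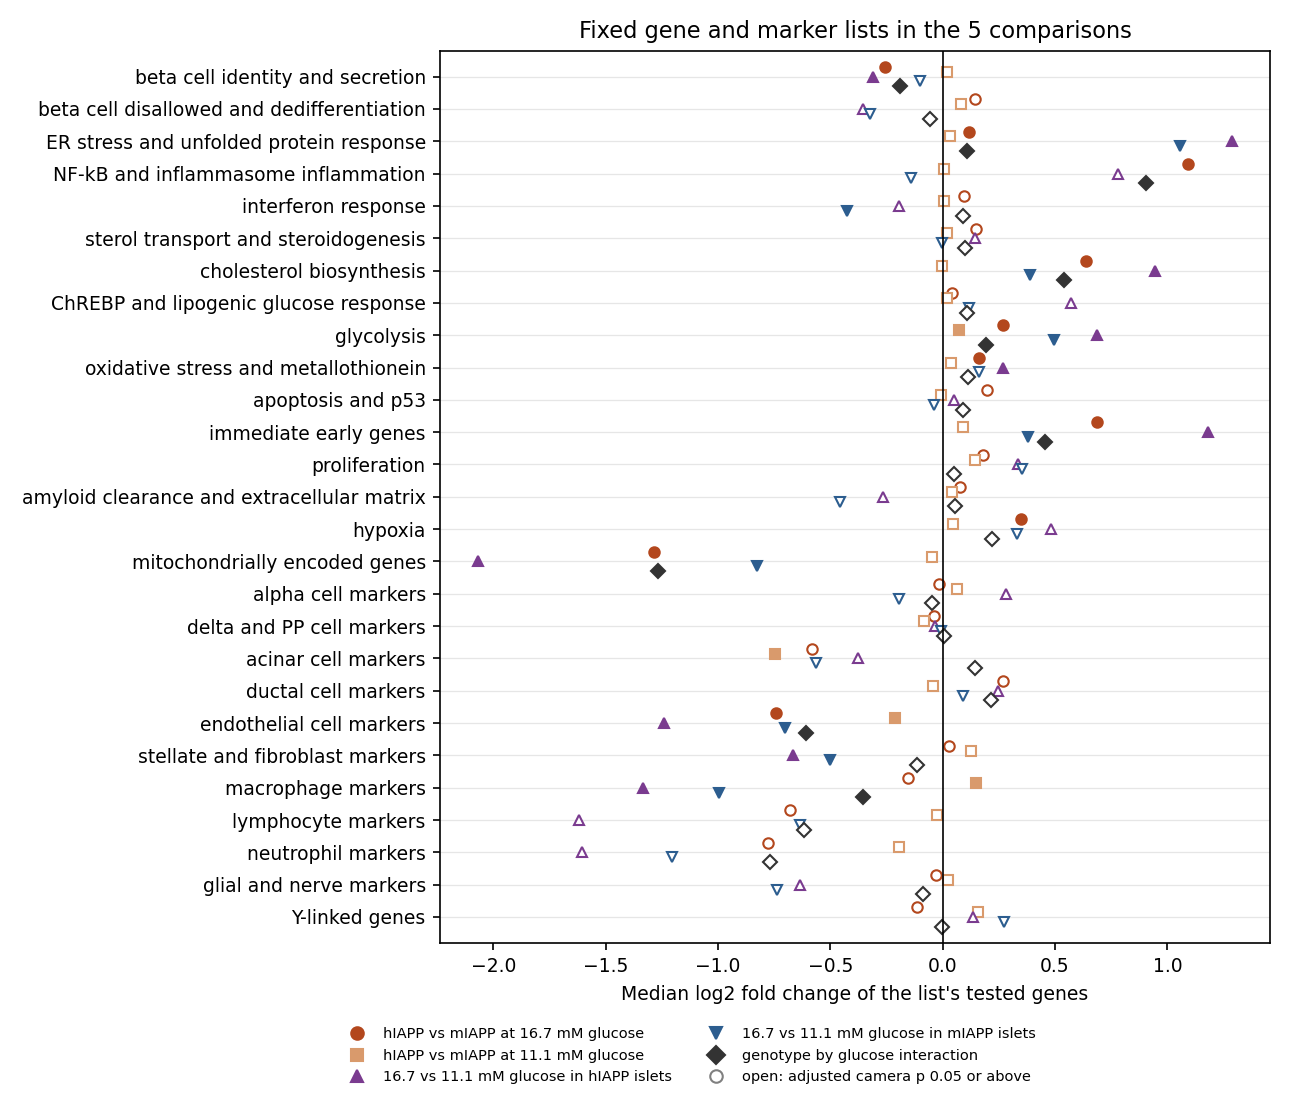
Median log2 fold change (horizontal axis) of the tested genes of each of the 27 fixed lists (vertical axis) in the 5 comparisons, each drawn with its own symbol and colour; filled symbols had a camera adjusted p under 0.05 and open ones did not. The cholesterol biosynthesis list lay at 0.64 and the NF-kB list at 1.09 for genotype at 16.7 mM glucose, and the macrophage list at -1.33 and -0.995 for glucose in hIAPP and mIAPP islets.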

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

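All tests of explanations and all splits in this part were chosen only after the results were seen, although the 20 Mb distance test near Iapp was laid out before. Patterns weighed against technical explanations come first, and further values that stood out follow.

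In hIAPP islets at 16.7 mM glucose the cholesterol biosynthesis list (median log2 0.64) and the NF-kB and inflammasome list (1.09) were higher, as was Star. With the mitochondrial covariate the medians were 0.502 and 0.962 and both lists still passed camera (adjusted p for the NF-kB list 1.88e-14). The medians that remained argue against the mitochondrial share as the whole cause. Passing camera adds little to this, since the other splits passed a median of 8 lists in the fit without the covariate. Without that covariate, camera with an estimated correlation passed 0 of the 27 lists in this comparison. The macrophage markers were not higher, with a median of -0.153 (SD of the members 0.458) in the fit without the covariate. In that fit olfactory and vomeronasal receptor genes fell too (medians -0.762 and -0.675), and lay at -0.03 and -0.004 with the covariate. The macrophage median therefore does not decide whether macrophages were more numerous. In 1 of 100 splits with genotype swapped inside sets, the real one, was either median as far from 0, the highest others being 0.61 and 1.017. As many lists as the 10 that passed were found in 32 of the 100 splits, with up to 13 in another, so the number of lists shows no more than chance. More macrophages in hIAPP islets stay open as an explanation. So do a response of islet cells to human IAPP and a change in the state of resident immune cells, which were not tested here.

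At 11.1 mM glucose 7 of the called genes besides Iapp lay within 20 Mb of it on chromosome 6, among them Hebp1, Gprc5a and Pik3c2g. Genes that near were called more often than genes on other chromosomes, with an odds ratio of 43.3 (95% interval 14.5 to 118). Within 5 Mb the odds ratio was 51.3 (5.48 to 237), and within 40 Mb 27.2 (9.13 to 74.1). DNA of the donor strain left beside the targeted locus is therefore a candidate explanation for these calls, Slco1a5 being uncertain because its span contains Iapp. The calls were not alike across glucose levels. At 16.7 against 11.1 mM, Gpr19 (0.91 and 1.09), Hebp1 (1.16 and 1.305) and Art4 (-3.26 and -3.20) had similar log2 fold changes. Pik3c2g (2.03 and 1.23), Gprc5a (2.63 and 1.30), BC049715 (0.65 and 1.555) and Slco1a5 (-0.11 and 0.72) did not. Whether strain variants change the expression of these genes or only the matching of reads, and whether some of them respond to human IAPP itself, was not tested.

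On other chromosomes 11 called genes, most of them olfactory, vomeronasal or predicted genes, were higher in hIAPP islets at both glucose levels, which reads of the replaced Iapp transcript counted under another gene could explain. In that case the excess counts should rise with glucose as Iapp does in hIAPP islets, by log2 0.711, and the difference from it was 0.133 for Nudcd1 (95% interval -0.095 to 0.362), 0.098 for Zfp488 (-0.205 to 0.401) and 0.085 for Olfr552 (-0.083 to 0.253), so this source may account for these 3. For Hist1h2aa (-1.5) and Cks1brt (-0.727) the difference argued against it (exact sign-flip p = 0.00781 each, adjusted p = 0.0286). Their excess at 16.7 mM glucose was 1.54 and 3.28 CPM. The test takes such reads to be a fixed share of the Iapp counts, which was not checked, so this source was not excluded. For Vmn1r213 (0.573), Gm13722 (0.391), Olfr477 (0.627), Olfr1238 (0.56), Gm47632 (-1.482) and Gm7291 (-2.387) the test left it open. For Gm7291 this was in spite of an adjusted exact sign-flip p of 0.0286, because its excess of 0.355 CPM at 16.7 mM glucose lay under a set minimum of 1 CPM. Without that minimum it would have gone with Hist1h2aa and Cks1brt. Expression of these genes in islets with human IAPP stays open for all 11, since the reads themselves were not used here.

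In each comparison the real split was the 1 of 100 with as many called genes. Each split swapped genotype at both glucose levels, or glucose in both genotypes, and fitted 1 spread for all groups. A real effect in 1 comparison thus widens the spread and lowers the calls of swapped splits in the others. The splits therefore do not test each comparison by itself, and cannot separate genotype or glucose from the mitochondrial share. The real numbers and the highest others were 3371 and 1863 for genotype at 16.7 mM glucose, 21 and 1 at 11.1 mM, 10768 and 9247 for glucose in hIAPP islets, 7805 and 4126 in mIAPP islets, and 513 and 34 for the interaction. The highest others, except at 11.1 mM glucose, swapped 1 of the 8 sets, so most of the real difference remained in them, and the 24 splits that swapped 4 sets gave 0 genes in edgeR. Splits gave as many lists past the threshold in 82 of 100 at 11.1 mM glucose (4 lists, highest other 13), 34 for glucose in hIAPP islets (10, highest other 14), 22 in mIAPP islets (9, highest other 13) and 14 for the interaction (9, highest other 11), so chance was not excluded for those numbers.

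The medians of single lists differed in how often a split came as far from 0. For genotype at 16.7 mM glucose, 1 of 100 splits, the real one, did so for the beta cell identity, immediate early and mitochondrially encoded genes too. The same held for 3 lists that did not pass camera: apoptosis genes (0.198), ductal markers (0.27) and neutrophil markers (-0.776). For the endothelial list 2 splits did so and for the hypoxia list 3. The adjusted p over the lists was 0.045 for each list with 1, 0.0692 for the endothelial and 0.092 for the hypoxia list. Chance was not excluded for the endothelial and hypoxia lists by these adjusted values. Nor was it for oxidative stress, with 5 (0.16, highest other 0.202), glycolysis, with 8 (0.268, highest other 0.368), or ER stress, with 11 (0.118, highest other 0.166). At 11.1 mM it was not excluded for any of the 4 lists past camera: macrophage 31, acinar 36, endothelial 42 and glycolysis 56. For glucose, the lists past camera had 1 of 100 splits each, except stellate markers in hIAPP islets with 2 (0.0692) and, in mIAPP islets, immediate early genes with 5 (median 0.381, highest other 0.428, adjusted p = 0.121) and mitochondrially encoded genes with 6 (-0.825, highest other 1.045, adjusted p = 0.142), so chance was not excluded for these 3. In the interaction, 2 of 100 splits came as far for the NF-kB list (0.906, highest other 0.993) and the cholesterol biosynthesis list (0.538, highest other 0.564), each with an adjusted p of 0.0692 over the lists. Immediate early and mitochondrially encoded genes had 2 too, endothelial markers 4, beta cell identity and macrophage markers 9 each, ER stress 19 and glycolysis 29. By the adjusted values chance was not excluded for any of these lists in the interaction.

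Single libraries lay far from the others of their group by a Dixon gap test in 10 of 49 groups of values tested. Chance would give 2.45 for normal values and independent tests. Some values here lay near 0 and some came from the same library, so the excess does not show more outliers than chance. The mIAPP library of set 7 at 16.7 mM glucose had 37% mitochondrial counts (nearest 13.4), 3.74% pseudogene counts (nearest 1.81) and a Cxcl1 level of 0.67 CPM. Acinar markers stood at 304 CPM in the mIAPP library of set 5 at 11.1 mM (nearest 150) and at 416 in the hIAPP library of set 2 at 11.1 mM (nearest 125). The mIAPP library of set 7 at 11.1 mM had the lowest total, 16.1 M (nearest 23). S100a9 stood at 22.7 CPM in the hIAPP library of set 6 at 16.7 mM (nearest 3.7) and at 0.124 in the hIAPP library of set 4 at 11.1 mM. In the mIAPP library of set 8 at 11.1 mM, Rdh16f1 was at 1.01 and Cxcl1 at 0.434.

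The response to glucose differed between hIAPP and mIAPP islets for 513 genes by the interaction test. Star was at log2 2.75, Cxcl1 at 5.84, Sprr1a at 4.81, Tac1 at 4.42, Lama3 at 4.33, Ccl2 at 4.19, Steap4 at 4.06, Slc4a11 at 3.59 and Klhl1 at 3.19. For Rdh16f1 and S100a9 the fitted coefficients were 10.78 and 10.62, but each has a group with 0 counts in all 8 libraries, so these depend on the prior count and are no fold. The call of Rdh16f1 ended without set 8, whose mIAPP library at 11.1 mM held 1.01 CPM with 0 as the nearest value of its group. Cxcl1 and Tac1 lie below the floor at 11.1 mM in both genotypes, so the size of their fitted coefficients (5.84 and 4.42) is uncertain. On the other side were Hpgd at -1.96, Cib3 at -1.70, Npas4 at -1.68, Otoa at -1.64 and Zdhhc22 at -1.51, and 5 with uncertain or scarce reads: Olfr586 at -1.80, Ccnb1ip1 at -1.58, Vmn2r27 at -1.55, Vmn1r72 at -1.51 and Olfr1310 at -1.46. Of these 5 calls, Vmn1r72 ended without set 1, 2, 3, 4, 7 or 8 (-1.41, -1.53, -1.48, -1.60, -1.36 and -1.48), Ccnb1ip1 without set 1, 4 or 8 (-1.48, -1.47 and -1.46), Vmn2r27 without set 1, 6 or 8 (-1.38, -1.55 and -1.54) and Olfr1310 without set 1 or 6 (-1.35 and -1.40). Without the mIAPP library of set 7 at 16.7 mM, Vmn1r72 (-1.33) and Ccnb1ip1 (-1.40) ended too. By the same test the list medians were 0.91 for NF-kB and inflammasome genes, 0.54 for cholesterol biosynthesis, 0.45 for immediate early genes, 0.19 for glycolysis and 0.11 for ER stress, and -0.19 for beta cell identity, -0.36 for macrophage markers, -0.61 for endothelial markers and -1.27 for mitochondrially encoded genes.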

How the results depend on the processing

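The covariate for the mitochondrial level, the libraries with under 10% mitochondrial counts and the omission of the mIAPP library of set 7 at 16.7 mM glucose were tests chosen only after the data were seen. For genotype at 16.7 mM glucose the 3371 genes became 1301 without the replicate block (1293 shared), 8240 with limma voom, 898 with the mitochondrial covariate (711 shared), 1149 in the 18 libraries under 10% mitochondrial counts (1040 shared) and 2108 without the mIAPP library of set 7, and 1623 to 3841 with 1 set left out. At 11.1 mM the 21 became 13 at 5 CPM, 35 with DESeq2, 46 with limma voom and 11 under 10% mitochondrial counts, and 15 to 24 with 1 set left out. For glucose in hIAPP islets the 10768 became 4169 with the mitochondrial covariate and 3916 under 10% mitochondrial counts (9764 to 10883 with 1 set left out), and the 7805 in mIAPP islets stayed within 1.5 times in all settings (6269 to 8508 with 1 set left out). The 513 of the interaction became 196 without the block, 959 with DESeq2, 4711 with limma voom, 953 with the Y-linked covariate, 304 with the mitochondrial covariate and 8 under 10% mitochondrial counts (239 to 558 with 1 set left out). The block moved no other number of called genes past 1.5 times. Fewer libraries were fitted under 10% mitochondrial counts and fewer genes at 5 CPM, and the cause of the other moves was not tested.

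Star kept its direction and its side of the threshold in all alternatives run: log2 2.81 to 3.14 for genotype at 16.7 mM glucose, 3.38 to 3.85 and 0.70 to 1.04 for glucose in hIAPP and mIAPP islets, 2.60 to 2.89 for the interaction, and 0.09 to 0.46, never past, at 11.1 mM. Iapp stayed lower in hIAPP islets at 16.7 mM (-1.34 to -1.10) and at 11.1 mM (-1.002 to -0.77), where it did not pass under 10% mitochondrial counts (-1.002). Of the 10 lists past the threshold at 16.7 mM, 4 at 11.1 mM, 10 and 9 for glucose and 9 in the interaction, camera with an estimated correlation passed 0 in each comparison, while fry passed 14, 0, 20, 15 and 7, which held 10, 0, 10, 8 and 4 of those lists. In the same order, 8, 2, 10, 7 and 9 lists passed with the mitochondrial covariate (7, 2, 9, 7 and 7 of them shared) and 11, 2, 12, 6 and 10 under 10% mitochondrial counts (8, 1, 10, 5 and 6 shared).

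Of 235 results for named genes, 208 kept their side of the threshold without the replicate block and 27 did not, 230 kept it with DESeq2 and 225 with limma voom, 184 with the mitochondrial covariate (44 no longer past, 6 reversed) and 153 under 10% mitochondrial counts (81 no longer past, 1 reversed). With 1 set left out, 213 to 226 kept it. The mitochondrial covariate reversed Tbata (0.21) and Vmn2r100 (0.11) for genotype at 16.7 mM glucose, and Impdh2-ps (0.98), Klf10 (0.53), Morf4l1-ps1 (-0.16) and Rpl10-ps3 (1.75) for glucose in hIAPP islets, where Impdh2-ps was also reversed under 10% mitochondrial counts (4.44); the cause was not tested.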

Other observations

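All tests in this part were chosen only after the data were examined: 15 gene families in 5 comparisons, 75 tests. The signal peptide and translocon genes, which bring proteins into the ER, rose with glucose in 19 of 23 cases in hIAPP islets (median log2 0.94, adjusted p = 5.51e-10; adjusted p = 0.158 with an estimated correlation) and in 21 of 23 in mIAPP islets (0.95, adjusted p = 2.58e-15; adjusted p = 0.0465 with an estimated correlation). Genes of COPI and COPII vesicle coats rose in 17 and 16 of 18 cases (0.63 and 0.55; adjusted p = 5.89e-07 and 3.55e-07; adjusted p = 0.204 with an estimated correlation in both), and aminoacyl-tRNA synthetases in 15 and 12 of 19 (adjusted p = 7.41e-06 and 5.06e-05; adjusted p = 0.201 and 0.204 with an estimated correlation). Cytosolic ribosomal protein genes fell in 73 and 64 of 80 cases (-0.67 and -0.47; adjusted p = 6.48e-11 in both; adjusted p = 0.554 with an estimated correlation), and in 5 and 49 with the mitochondrial covariate.

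For genotype at 16.7 mM glucose, dual-specificity phosphatases, which switch off MAP kinases, were higher in 9 of 19 cases and lower in 1 (adjusted p = 2.39e-05; adjusted p = 0.162 with an estimated correlation), and keratins were higher in 4 of 13 (adjusted p = 0.0284; adjusted p = 0.262 with an estimated correlation). Olfactory receptor genes were lower in 74 of 244 cases and higher in 5 (median -0.76, adjusted p = 6.32e-13; adjusted p = 0.486 with an estimated correlation), and lower in 6 with the mitochondrial covariate. Vomeronasal receptor genes were lower in 43 of 129 (adjusted p = 3.73e-11; adjusted p = 0.502 with an estimated correlation), and in 0 with that covariate. With glucose in hIAPP islets, 201 olfactory and 103 vomeronasal receptor genes were lower and 7 and 1 higher. In mIAPP islets 33 and 14 were lower and 4 and 1 higher. With the covariate 8 and 2 were lower in hIAPP islets, and 4 and 4 in mIAPP islets.

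Among the 31 genes that passed in opposite directions with glucose in hIAPP and mIAPP islets, a large difference is fixed by that choice, so no test of it is given. Icam1, an adhesion molecule for leukocytes, rose by log2 0.70 in hIAPP islets and fell by 0.80 in mIAPP islets, as did Gbp6, an interferon-induced GTPase (0.85 and -0.89), and Mmp12, a macrophage elastase (0.61 and -0.50). Defb1, a defensin, moved the other way (-1.02 and 0.35). These genes were chosen after their values were seen.

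S100a8, the partner of S100a9, stood at 1.3 ± 2.7 CPM (SD, n = 8) in hIAPP islets at 16.7 mM glucose, with 7.96 in set 6, and was too low to be tested. The neutrophil receptor genes Csf3r and Cxcr2 were at 0.45 and 1.87 there against 0.785 and 3.82 in mIAPP islets, and the neutrophil genes Ly6g and Ngp at 0.

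The log2 fold changes moved with the GC content of the genes, most for genotype at 11.1 mM glucose, with a Spearman r of -0.514 across 16206 genes, which are not independent replicates. The values were -0.099 for genotype at 16.7 mM, -0.142 and -0.307 for glucose in hIAPP and mIAPP islets, and 0.147 for the interaction, and for gene length they lay between 0.13 and 0.191.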
